A study of Drosophila melanogaster with 8 samples.

How the data were processed

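The series compared embryos of the laboratory wild-type strain Oregon R (OrgR) with embryos mutant for extra sex combs (esc). The esc gene encodes a WD40-repeat subunit of Polycomb repressive complex PRC2, which methylates histone H3 at lysine 27. Per the labels, the mutants lacked esc function both maternally and zygotically, and each library came from a pool of at least 200 whole embryos of stages 14 and 15. Total RNA was made into unstranded libraries and sequenced as paired reads of 150 bp on an Illumina HiSeq instrument, per the labels' protocols. There were 8 libraries, 4 of each genotype, titled 1-1, 1-2, 2-1 and 2-2 within a genotype.

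The authors deposited one table of 17321 genes with an RPKM value (reads scaled to gene length and to the mapped reads of the library) for each of the 8 libraries, on a linear scale and unfiltered per the labels. The genome build was dm6, per the submitters' processing notes. The aligner, the counting program and the gene models were not given in the sources used here. The lowest value was 0.001 RPKM, which filled 27.6% of all cells, and 3839 genes held it in all 8 libraries, so it was treated as a floor and not as a measurement. RPKM values are shares of a library: where some genes take a larger share of the reads, the values of all other genes become lower. Reads were not assigned by strand, so a gene and an overlapping gene on the other strand share reads.

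Gene symbols were matched to the Ensembl release 115 annotation, whose coordinates are those of dm6. This gave a position for 16319 symbols, of which 12678 matched directly and 3641 through a synonym. All positions are 1-based.

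Whole read numbers could not be recovered from RPKM values, but the relative depth of the libraries could. Genes with the same small number of reads in a pair of libraries have the same ratio of RPKM values, and this ratio formed a peak among values between 0.06 and 1.5 RPKM in each of the 28 pairs, from 3.87 to 7.36 times the median density. The depths so obtained lay between 84.4% and 100% of that of the deepest library, and combining 2 pairs missed the peak of the pair that closed the triangle by at most 0.004 on the log2 scale. Depth therefore differed little between libraries, and the precision of each value is given by the spread between sets.

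The titles do not say whether the second number marks a repeat library of one embryo pool. The 2 libraries that share a genotype and a first number (a set) were therefore averaged on the log2 scale, and the 4 set means, 2 per genotype, were compared. This design, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Nothing in the labels says that the sets were separate collections of embryos, so the p-values measure the spread between these sets, which may be technical. Values are given as mean ± SD of the 2 set means of a genotype.

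Genes with a mean of at least 0.5 RPKM over the 8 libraries were tested on log2(RPKM + 1) with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a trend in the variance. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. The fit left 2 residual degrees of freedom, and 4.55 after moderation across genes. All fold changes called log2 are on the log2(RPKM + 1) scale, which understates the change of genes with low values, and their errors are standard errors of the fit.

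For 25 gene lists, the members that rose, fell or did not pass were counted, both with the adjustment over all genes and adjusted over the list alone. Each list was compared with all other genes by limma's camera test with a preset inter-gene correlation of 0.01, adjusted over the 25 lists. The test was repeated with the correlation estimated from the data, which has little power with so few residual degrees of freedom. The relation of fold change to gene order over the 8 Hox genes was tested by exact permutation of the order. The named genes were fixed by rule. They were the members of the Polycomb complex list, the 8 Hox genes, and the 10 largest rises and 10 largest falls among changed genes with a mean of at least 1 RPKM and no overlap between the 4 libraries of each genotype. Symbols that are only a number were skipped, 2 among the rises and 13 among the falls. From each list, up to 2 members with the largest rise and up to 2 with the largest fall were added, or the 2 with the smallest p where none passed. The rule gave 111 genes.

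The fit was tested on simulated data in which 200 of 10543 genes were changed. Gene means were those of the OrgR libraries, and spreads within sets were those of the real genes. The spread of each gene between sets was averaged with the median spread, which tempers the noisiest genes. Changed genes were not drawn from those with the lowest OrgR means. They were also far fewer than the genes called in the real data, so the rates below need not hold there. Of 25 genes changed by each amount, all 25 were called at log2 changes of -2, 2, 3 and 4, 24 at -1, 23 at 1, 11 at -0.6 and 14 at 0.6. Of the simulated calls, 6.01% were false.

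Alternatives tried were pseudocounts of 0.1 and 0.5, no filter and a filter at 2 RPKM, median-of-ratios, quantile and TPM scaling, other settings of eBayes, the 8 libraries fitted as independent or with a correlation within sets, 1 library per set, a block for the title number, each library and each set left out, and other set tests. Centring on the median gene and a block with the set numbers crossed were added later. Plots and the remaining tests were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Of the listed genes, those not found in the table or under the filter were left out of the tests.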

Results

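RNA from whole embryos of stages 14 and 15, when organs and the larval nervous system differentiate, was measured in Oregon R controls (OrgR) and in maternal and zygotic esc mutants. Each genotype had 4 libraries in 2 sets. Relative depth ranged from 84.4% of the deepest library (esc 2-2) to 100% (esc 1-2), with OrgR libraries from 86.0% (OrgR 1-2) to 98.3% (OrgR 2-2). Over 7032 genes with a mean of at least 10 RPKM, the median absolute log2 difference was 0.03 to 0.06 between the libraries of a set, 0.12 to 0.16 between sets of one genotype and 0.38 to 0.48 between genotypes. The 2 libraries of a set were averaged and counted as 1 sample.

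The level of esc itself was lower in each mutant library. It was 10.7, 12.4, 11.9 and 11.7 RPKM in OrgR libraries 1-1, 1-2, 2-1 and 2-2, and 3.59, 3.56, 4.40 and 3.66 RPKM in the esc libraries of the same numbers. The mean went from 11.7 ± 0.19 RPKM in OrgR to 3.80 ± 0.32 RPKM in esc (SD, n = 2 sets each), a log2 change of -1.40 ± 0.11 (SE, limma adjusted p = 0.00267). Transcripts of esc were therefore still present in the mutants at about 3.07-fold lower level. The gene lies on chromosome arm 2L from 11827204 to 11829405 in dm6, on the minus strand, inside the span of Pde1c and with no base of its exons in an exon of another gene. Genes near it fell and rose, and those named here were chosen after their values were seen. Of the 12 other tested genes within 100 kb, 3 fell and 5 rose. Those that fell were crol, which encodes a zinc finger transcription factor (2L, 11794327 to 11809438, log2 change -1.38 ± 0.19), CycY, which encodes a cyclin (11810092 to 11813780, -1.43 ± 0.15), and the phosphodiesterase gene Pde1c (11814156 to 11928572, -1.07 ± 0.17). Their adjusted p-values were 0.00817, 0.00442 and 0.0112. CG14937, next to crol on the other side, had a log2 change of -0.12 (adjusted p = 0.408), while 4 genes within the Pde1c span at higher coordinates than esc rose. These were CG44008 (log2 change 1.57, adjusted p = 0.00988), CG14933 (0.92, adjusted p = 0.036), CG42486 (0.83, adjusted p = 0.0237) and Mal-B1, a maltase gene (2.71, adjusted p = 0.0013), whereas Mal-B2 beside it did not pass (0.00, adjusted p = 0.99). The fifth rise was that of Vha100-5, a vacuolar ATPase subunit gene (3.96, adjusted p = 0.00194).

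**Figure D1:**
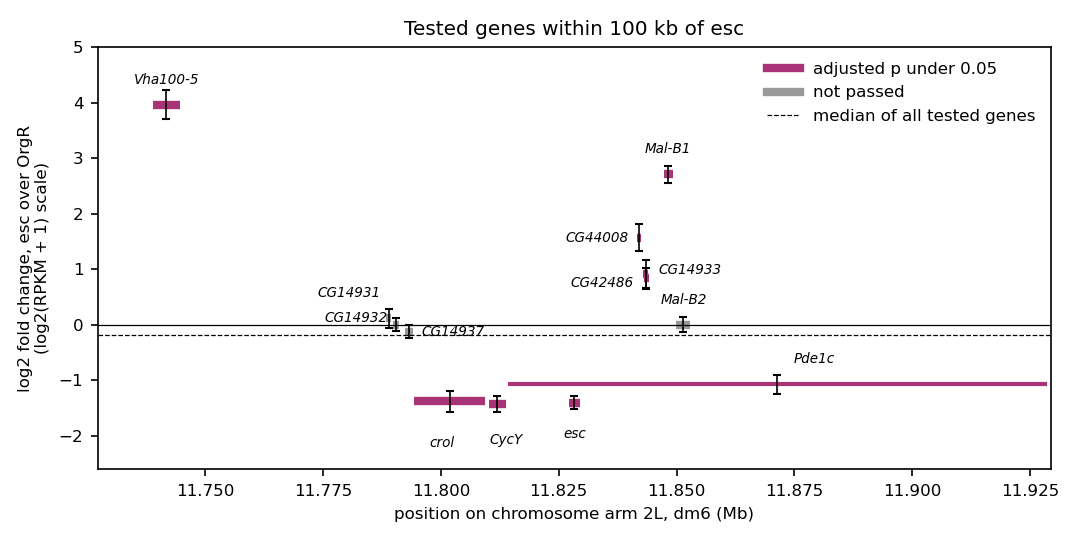
Log2 fold change of esc over OrgR (log2(RPKM + 1) scale) for tested genes within 100 kb of esc, drawn at their annotated positions on chromosome arm 2L in dm6; bars span the gene and whiskers are the standard error of the fit. The genes crol, CycY, esc and Pde1c lie at or below -1.07, while CG14937 at -0.12, CG44008 at 1.57 and Mal-B1 at 2.71 lie above them.

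The study's title asks about Hox genes, the homeobox genes that specify segment identity along the anterior-posterior axis, and these moved in opposite directions. Abd-B, the most posterior of them, rose from 57.1 ± 4.9 RPKM in OrgR to 327 ± 38 RPKM in esc, 5.73-fold (log2 change 2.50 ± 0.12, adjusted p = 0.00108). The most anterior, lab, fell from 15.3 ± 1.1 to 1.38 ± 0.028 RPKM (log2 change -2.77 ± 0.11, adjusted p = 0.000675). Ubx, which specifies the posterior thorax and anterior abdomen, fell from 33.7 ± 6.0 to 7.24 ± 0.57 RPKM (log2 change -2.06 ± 0.16, adjusted p = 0.00249). For pb the change was smaller, from 4.90 ± 0.17 to 3.24 ± 0.18 RPKM (log2 change -0.48 ± 0.11, adjusted p = 0.0233).

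The other 4 Hox genes did not pass. Their log2 changes were 0.17 for Dfd (15.3 and 17.3 RPKM in OrgR and esc, adjusted p = 0.299), -0.41 for Scr (14.6 and 10.3 RPKM, adjusted p = 0.299), -0.52 for Antp (35.0 and 24.2 RPKM, adjusted p = 0.0606) and -0.33 for abd-A (56.4 and 44.6 RPKM, adjusted p = 0.219). For Scr the SD of the OrgR sets was 6.1 RPKM. Antp passed in 6 of 28 other settings, among them without esc library 1-1 (adjusted p = 0.0267) and with a correlation within sets (adjusted p = 0.0409), and abd-A passed with set numbers crossed (adjusted p = 0.0202). Exons of Antp overlap those of another annotated gene over 50.1% of their bases, so its value is uncertain. The Antennapedia complex genes lie on chromosome arm 3R from 6661427 (lab) to 6999228 (Antp), and the bithorax complex genes from 16656623 (Ubx) to 16972236 (Abd-B). In all, 1 of 8 Hox genes rose, 3 fell and 4 did not pass, both over all genes and adjusted over the list alone. The list as a whole did not shift to one side of other genes (camera adjusted p = 0.492). That test looks for a shift in one direction, so opposite moves cancel in it, and it does not show the Hox genes unchanged. Fold change did not follow gene order from lab to Abd-B across these 8 genes, which are not independent replicates (Spearman rho = 0.50, exact permutation p = 0.216; Pearson r = 0.576, exact permutation p = 0.128). Of the genes of these complexes outside the Hox class, Ama, an immunoglobulin-domain gene, fell from 554 to 262 RPKM (log2 change -1.08), and ftz, a pair-rule gene, fell from 1.22 to 0.473 RPKM (log2 change -0.59). These 2 of 5 listed genes were the only ones tested, and both also fell adjusted over the list alone (camera adjusted p = 0.142). The call of pb ended in 7 of 28 settings, among them median-of-ratios scaling (adjusted p = 0.0853) and each left-out set (adjusted p = 0.0956 without OrgR set 1, 0.0853 without OrgR set 2, 0.0606 without esc set 1 and 0.0959 without esc set 2). Those of lab, Ubx and Abd-B held in all 28 settings tried.

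**Figure D2:**
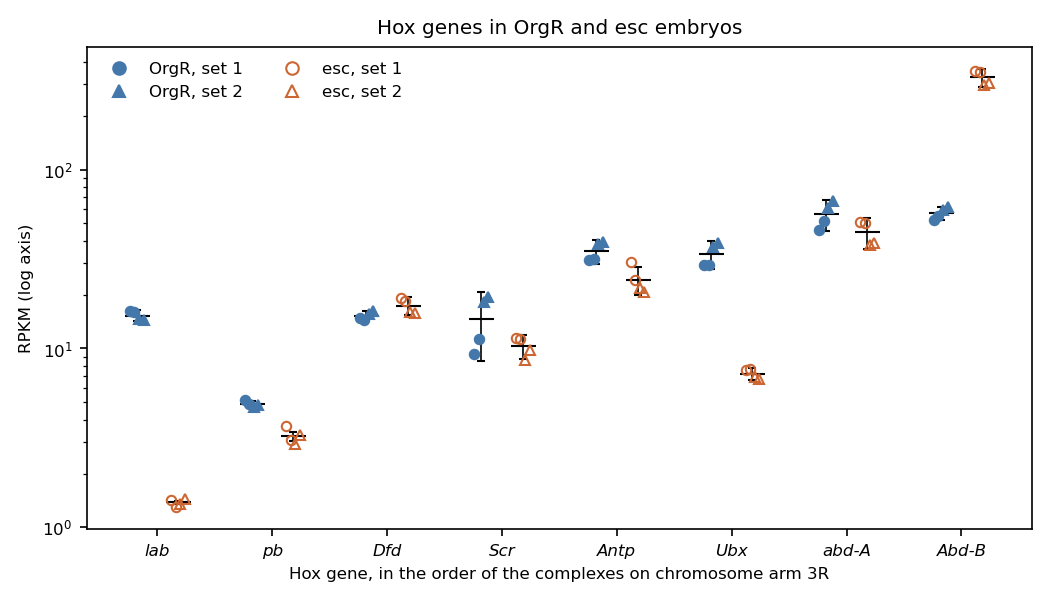
RPKM (log axis) of the 8 Hox genes in each library, by genotype and set, in their order along chromosome arm 3R; black lines are the mean and SD of the 2 set means of a genotype. The 4 esc libraries lie between 296 and 355 RPKM for Abd-B, above all OrgR libraries, and between 1.30 and 1.45 RPKM for lab, below all OrgR libraries.

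Across the transcriptome, 58 of 70 tested late cuticle protein genes (of 95 in the table) and 15 of 25 muscle genes rose. Falls were seen in 26 of 34 cell cycle genes, 20 of 27 neural progenitor genes and 23 of 32 anterior and brain transcription factor genes. As lists, each of these differed from other genes with a preset correlation and not with an estimated one (adjusted p = 0.76 with an estimated correlation). Whether the esc pools were older than the OrgR pools was weighed below only for the late cuticle and Hox genes. In none of the lists can pool age be told apart from an effect of the genotype. Of 10547 tested genes, 5537 changed, of which 2208 rose and 3329 fell. Of these, 1529 changed at least 2-fold, and 1330 of them rose and 199 fell. The rises reached much further than the falls, as 119 genes rose by at least 5 on the log2 scale. The median log2 change of all tested genes was -0.18, and it was 0.00 under median-of-ratios scaling, so that small falls depend on the scaling. Rises made up 39.9% of the changed genes as deposited, 67.4% of 3825 under median-of-ratios scaling and 66.0% of 4055 after centring on the median gene. Among genes changed at least 2-fold, rises made up 87.0% as deposited and 68.3% after quantile normalization. The number of changed genes was lower with one set fewer, at 2700 without OrgR set 1, 2087 without OrgR set 2, 3182 without esc set 1 and 2306 without esc set 2, where the lone set is assumed to vary like the sets of the other genotype. Rises were then the majority without any change of scaling, at 60.3%, 63.0%, 56.8% and 65.8% of the changed genes in this order, and at 63.6% of 2467 with the set number as a block.

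The 10 largest named rises were almost all genes of the cuticle, the chitin and protein coat secreted by the epidermis. Cpr65Ea, which encodes a protein with a chitin-binding consensus, went from 1.54 ± 0.067 RPKM in OrgR to 1815 ± 888 RPKM in esc (log2 change 9.39 ± 0.35, adjusted p = 0.000576; 3L, 7086003 to 7086608). TwdlF, of the Tweedle family of cuticle proteins, went from 1.78 ± 0.13 to 1158 ± 40 RPKM (log2 change 8.71 ± 0.09, adjusted p = 0.000108; 3R, 4247020 to 4248313). TwdlM went from 2.08 to 1754 RPKM, Cpr64Ad from 1.38 to 1022 RPKM and TwdlL from 0.981 to 712 RPKM. The near-identical copies Lcp65Ag1, Lcp65Ag2 and Lcp65Ag3, larval cuticle genes, rose by 8.84, 8.61 and 9.14, and Cpr65Ax1, which also has a close copy, by 8.61; reads of such copies cannot be assigned with certainty. Exons of Lcp65Ag3 also lie wholly (100%) within those of an antisense gene, so its value is uncertain on that count too. Ipod, on the X chromosome from 10231002 to 10233080, went from 1.57 ± 0.20 to 778 ± 63 RPKM (log2 change 8.25 ± 0.11, adjusted p = 0.000179). For many cuticle genes the esc sets differed widely, and the SD of Cpr65Ax1 in esc was 830 RPKM around a mean of 927 RPKM.

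The 10 largest named falls were more varied and included Hox genes and a Hox cofactor. Drsl5, a drosomycin-like peptide gene, fell from 946 ± 186 to 71.9 ± 3.4 RPKM, 13.2-fold (log2 change -3.69 ± 0.16, adjusted p = 0.000757; 3L, 3316781 to 3317144). It was followed by lab and by Hsc70-2, a heat shock cognate gene (log2 change -2.35). Next came Vha100-4, a vacuolar ATPase subunit gene (-2.07), then Ubx, phu (-2.04), the homeobox gene unpg (-1.95), link (-1.92), hth and the cytochrome P450 gene Cyp12a4 (-1.88). The homeobox gene hth, whose product binds DNA together with Hox proteins, fell from 109 ± 20 to 28.4 ± 4.2 RPKM (log2 change -1.90 ± 0.18, adjusted p = 0.00368; 3R, 10507561 to 10639568).

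Of 25 gene lists, 11 differed from other genes in the camera test with the preset correlation, 4 upward and 7 downward. With an estimated correlation none of them passed, and the smallest adjusted p was 0.76. At an unadjusted p under 0.05 the count was also 0. This version rests on 2 residual degrees of freedom and has little power, so a list that did not pass it is not shown to be unchanged. In the 11 lists that passed with the preset, the estimated correlation ran from 0.027 (neural progenitor genes) to 0.567 (late cuticle proteins). These estimates are uncertain, but all lay above the preset 0.01, so the camera p-values with the preset may be much too small. The fry test of limma, which does not compare a list with other genes, called 6. List medians are given below relative to the median of all tested genes.

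Late cuticle protein genes had the highest median of the 25 lists. Of 95 members in the table, 70 passed the filter on the mean of all 8 libraries, which a gene can pass by its level in esc alone. Of these 70 tested members, 58 rose, 2 fell and 10 did not pass, and 61 rose and 2 fell adjusted over the list alone. Their median lay 4.10 above that of all genes (camera adjusted p = 2.6e-21; adjusted p = 0.76 with an estimated correlation). The members that fell were Cpr49Ac (7.67 to 2.23 RPKM, log2 change -1.43) and Cpr72Ec (1.47 to 0.64 RPKM, -0.60, past the threshold in 21 of 27 other settings). In the list 1 gene fell after centring or under median-of-ratios scaling and 5 after quantile normalization. Summed over the list, these genes made up 0.016% to 0.0186% of all RPKM in the OrgR libraries, 0.771% and 0.773% in esc set 1, and 1.44% and 1.50% in esc set 2. The broader epidermis and cuticle list also rose, with 9 of 19 members up, 2 down and 8 not passed, the same counts adjusted over the list alone, and a median 0.65 above that of all genes (camera adjusted p = 0.02; adjusted p = 0.76 with an estimated correlation; adjusted p = 0.0876 without esc set 1). Its largest rises were the catecholamine enzyme genes used in cuticle tanning, Ddc (0.444 to 13.1 RPKM, log2 change 3.10 ± 0.51) and ple (4.73 to 30.7 RPKM, 2.50 ± 0.29). Its falls were sn, which encodes the actin bundler fascin (-0.63), and mwh, a planar polarity gene (-0.50), and none of the 19 fell after centring or under median-of-ratios scaling.

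Most of the muscle genes that passed the test rose. Of 25 members, 15 rose, 2 fell and 8 did not pass, and 16 rose and 2 fell adjusted over the list alone. Their median lay 1.03 above that of all genes (camera adjusted p = 2.57e-05; adjusted p = 0.76 with an estimated correlation). Mlp60A, a muscle LIM protein gene, went from 282 ± 72 to 2304 ± 417 RPKM (log2 change 3.04 ± 0.23, adjusted p = 0.00238), and Prm, the paramyosin gene, from 63.2 ± 26 to 336 ± 7.0 RPKM (2.45 ± 0.29, adjusted p = 0.0058). The members that fell were the transcription factor genes nau (20.8 to 11.4 RPKM, -0.82), which shares 26.4% of its exonic bases with another gene, and lmd (24.1 to 15.3 RPKM, -0.62). Ribosomal protein genes were the remaining list above other genes (camera adjusted p = 0.00195; adjusted p = 0.932 with an estimated correlation), by a median of 0.31. Only 2 of 90 members rose, RpL39 (log2 change 0.39) and RpS20 (0.29), 4 fell, among them RpS10a (-0.87) and RpLP0-like (-0.81), and 84 did not pass; adjusted over the list alone none passed, although 24 members rose after centring. After quantile normalization the list's median was -0.0049 and the call ended (adjusted p = 0.246), as it did without OrgR set 2 (adjusted p = 0.0656) and without esc set 2 (adjusted p = 0.136).

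As deposited, most, not all, of the listed transcription factor genes of the head and brain fell, and so did most of the other listed Polycomb targets. Of 32 anterior and brain transcription factor genes, 23 fell and none rose, 26 fell adjusted over the list alone and 18 after centring, with a median 0.50 below that of all genes (difference -0.50, camera adjusted p = 1.63e-05; adjusted p = 0.76 with an estimated correlation). The NK-class homeobox gene scro fell from 24.1 ± 1.6 to 7.55 ± 1.1 RPKM (log2 change -1.56 ± 0.13, adjusted p = 0.0031), and the homeobox gene Ptx1 from 62.1 ± 3.7 to 22.5 ± 0.44 RPKM (-1.42 ± 0.09, adjusted p = 0.0019). Of 41 other developmental regulators known as Polycomb targets, 32 fell, 1 rose and 8 did not pass, and 35 fell and 1 rose adjusted over the list alone. After centring 21 of them fell, and under median-of-ratios scaling 20. The median difference of the 41 from all genes was -0.41 (camera adjusted p = 3.91e-06; adjusted p = 0.76 with an estimated correlation). The homeobox gene unpg (12.3 to 2.43 RPKM) and the segment polarity gene gsb (22.3 to 7.23 RPKM, log2 change -1.50) fell furthest, and the posterior gut regulator cad was the one that rose (23.6 to 34.9 RPKM, log2 change 0.55, adjusted p = 0.0116).

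Most of the listed cell cycle and neural progenitor genes fell as well. Of 34 cell cycle genes, 26 fell, 1 rose and 7 did not pass, the same counts adjusted over the list alone, and 20 fell after centring; their median difference from all genes was -0.50 (camera adjusted p = 7.75e-06; adjusted p = 0.76 with an estimated correlation). The mitotic cyclin genes CycB3 (40.3 ± 1.8 to 16.8 ± 0.027 RPKM, log2 change -1.21) and CycB (68.1 ± 6.4 to 29.9 ± 0.66 RPKM, -1.16) fell most, and trbl, which restrains mitosis, rose (21.5 to 32.6 RPKM, 0.57). Of 27 neuroblast and neural progenitor genes, 20 fell, 22 adjusted over the list alone and 18 after centring, with a median difference of -0.60 (camera adjusted p = 2.66e-05; adjusted p = 0.76 with an estimated correlation). These included the proneural gene ase (12.6 to 5.37 RPKM, -1.09) and the snail-class gene esg (62.0 to 28.7 RPKM, -1.09). Of 8 temporal factors of neuroblasts, 5 fell, also adjusted over the list alone, but only 2 after centring or under median-of-ratios scaling, led by cas (72.6 to 34.8 RPKM, -1.04) and svp (27.2 to 17.0 RPKM, -0.65), and the list did not pass (camera adjusted p = 0.0569). It passed in 6 other settings, among them without OrgR library 2-1 (adjusted p = 0.0497), OrgR set 1 (adjusted p = 0.0334) and esc set 1 (adjusted p = 0.0406).

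Among genes for chromatin regulators of the Polycomb and trithorax groups, the falls were small and their number depended on the scaling. Of 20 Polycomb complex genes, 16 fell, with a median difference of -0.38 from all genes (camera adjusted p = 0.00126; adjusted p = 0.76 with an estimated correlation), and 17 fell adjusted over the list alone. After esc, the largest fall was that of Psc (16.1 ± 3.1 to 8.71 ± 0.52 RPKM, log2 change -0.81). The gene escl, the close relative of esc, went from 8.36 to 6.20 RPKM (-0.38, adjusted p = 0.0479), and E(z), the PRC2 methyltransferase gene, from 23.0 to 16.8 RPKM (-0.44, adjusted p = 0.0196). Su(z)12, Jarid2, Pc and Su(z)2 did not pass (adjusted p = 0.191, 0.142, 0.0521 and 0.795). After centring only 6 of the 20 fell, 1 adjusted over the list alone, and 5 under median-of-ratios scaling, escl and E(z) did not pass under median-of-ratios scaling (adjusted p = 0.244 and 0.108), and escl passed in only 14 of 28 settings. Of 14 trithorax group genes, 7 fell, 7 adjusted over the list alone, 5 after centring and 2 under median-of-ratios scaling, with a median difference of -0.39 (camera adjusted p = 0.0151; adjusted p = 0.76 with an estimated correlation; adjusted p = 0.0645 after quantile normalization). They included mor (84.3 to 50.5 RPKM, -0.73) and brm (42.2 to 26.2 RPKM, -0.67), which encode subunits of the Brahma remodelling complex. Of 17 genes of early embryogenesis, 8 fell, also adjusted over the list alone, and 5 after centring, with a median difference of -0.33 (camera adjusted p = 0.0151; adjusted p = 0.76 with an estimated correlation; adjusted p = 0.0819 with the filter at 2 RPKM). The largest falls were those of the pair-rule gene prd (2.65 to 0.663 RPKM, -1.13) and the mesoderm gene sna (69.3 to 34.9 RPKM, -0.97), which is also on the neuroblast list.

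**Figure D3:**
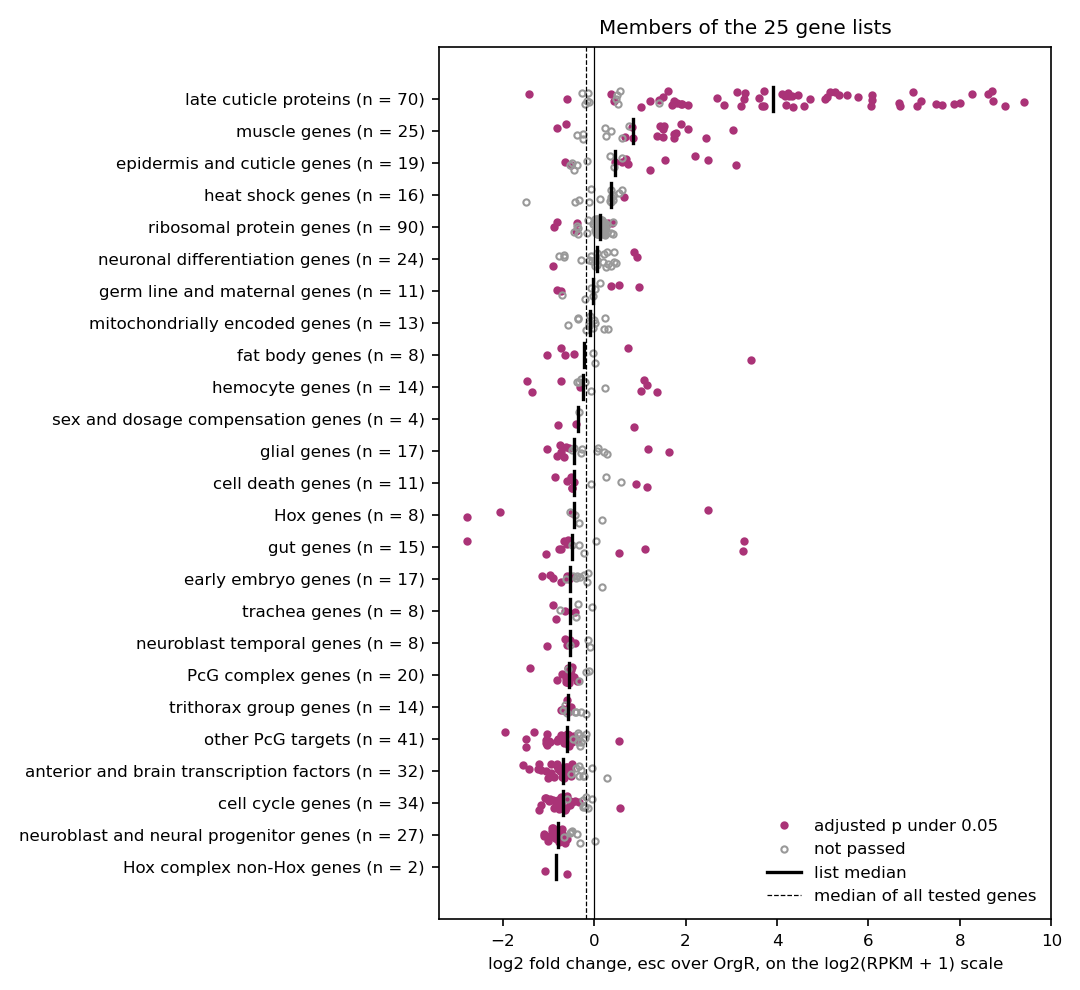
Log2 fold change of esc over OrgR (log2(RPKM + 1) scale) for each tested member of the 25 gene lists, with filled points for genes past the adjusted p threshold; thick bars are list medians, and the dashed line is the median of all tested genes at -0.18. Late cuticle proteins lie furthest to the right, and the neural progenitor, cell cycle and transcription factor lists lie left of the dashed line; these medians kept their sign under each scaling tried.

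The glial, neuronal, hemocyte, gut and fat body lists held rises and falls side by side and did not pass as lists. Among glial genes 2 of 17 rose, the glutamate transporter gene Eaat1 (0.214 to 2.80 RPKM, log2 change 1.64) and the astrocyte gene alrm (14.2 to 33.8 RPKM, 1.19), and 7 fell, led by the glial fate gene gcm (33.1 to 15.8 RPKM, -1.02) and pnt (-0.80), with camera adjusted p = 0.664. Of 24 neuronal differentiation genes, Snap25 (0.94) and Gad1 (0.86), of the synapse and of GABA synthesis, rose, nerfin-1 fell (-0.91) and 21 did not pass (camera adjusted p = 0.181, and 0.0298 without esc set 2); the call of Gad1 ended after quantile normalization (adjusted p = 0.139). Of 14 hemocyte genes, 4 rose, led by the type IV collagen genes vkg (47.9 to 125 RPKM, 1.37) and Col4a1 (83.6 to 188 RPKM, 1.17), and 4 fell, led by the crystal cell prophenoloxidase genes PPO2 (267 to 95.9 RPKM, -1.47) and PPO1 (145 to 56.0 RPKM, -1.36), with camera adjusted p = 0.909. Of 15 gut genes, 4 rose, led by the digestive enzyme genes Try29F (3.27) and Mal-A1 (3.25), and 7 fell, led by lab and wg (-1.05), with camera adjusted p = 0.53. Of 8 fat body genes, 2 rose, Adh (91.6 to 968 RPKM, 3.44) and FASN1 (0.73), and 4 fell, led by Lsp2 (-1.03) and srp (-0.72), with camera adjusted p = 0.909. Exons of Adh are shared over 93.9% of their bases with Adhr, and those of Lsp2 over 84.6% with an antisense gene, so both values are uncertain. Adjusted over the list alone, the numbers that rose and fell were the same in the glial, neuronal, hemocyte and fat body lists, and were 4 and 9 in the gut list. Under median-of-ratios scaling they were 4 and 4 in the glial list, 4 and 1 in the neuronal list and 2 and 2 in the fat body list.

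The remaining lists did not pass either. Among 11 cell death genes, the death inducers skl (26.1 to 59.4 RPKM, log2 change 1.16 ± 0.09) and rpr (43.0 to 81.6 RPKM, 0.91 ± 0.09) rose, while 6 genes fell, led by the initiator caspase gene Dronc (25.5 to 13.7 RPKM, -0.85) and its activator Dark (-0.60). Adjusted over the list alone 4 rose and 6 fell (camera adjusted p = 0.904), after centring 4 rose and 4 fell, and under median-of-ratios scaling 4 rose and 2 fell. Exons of Dark overlap an antisense gene over 56.9% of their bases. Of 11 germ line genes, 3 rose, led by piwi (0.99) and nos (0.53), and 2 fell, aub (-0.81) and vas (-0.72), with camera adjusted p = 0.784. After quantile normalization 2 rose and 6 fell, and the gene nos had a log2 change of -0.029 (adjusted p = 0.882, range over its alternatives 0.00142 to 0.882). Of 8 tracheal genes, 4 fell, led by kni (-0.90) and sinu (-0.83), and 6 fell adjusted over the list alone, but only 1 after centring or under median-of-ratios scaling (camera adjusted p = 0.088, but 0.0334 without OrgR set 1 and 0.0366 without esc set 1). Of 4 sex and dosage compensation genes, dsx rose (0.87) and tra (-0.79) and msl-2 (-0.39) fell (camera adjusted p = 0.884), but none of the 4 fell after centring or under median-of-ratios scaling. These counts were unaltered adjusted over the list alone in the germ line and sex lists. Of 16 heat shock genes, only stv passed (20.2 to 32.2 RPKM, 0.66), and none did adjusted over the list alone (camera adjusted p = 0.528, but 0.000887 without OrgR set 1). None of 13 mitochondrially encoded genes changed (camera adjusted p = 0.884); the smallest p-values were those of ND2 (log2 change -0.57, adjusted p = 0.118) and COX1 (0.30, adjusted p = 0.22), at 86.2 and 57.0 RPKM and at 2110 and 2597 RPKM in OrgR and esc. The mean of the gut and fat body lists was positive (0.01 and 0.17) while their median was negative (-0.49 and -0.23), and the hemocyte, germ line and mitochondrial lists had medians of -0.24, -0.03 and -0.09 with a test directed upward. The medians of the neuronal, germ line and mitochondrial lists changed sign under other scalings.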

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

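Single libraries that stood apart from the other 3 of their genotype were searched for among the 111 named genes and 4 library measures. Of 230 groups of 4 libraries, 6 had a library that stood apart. For 4 independent values chance would give about 1 in 20, or 11.5. Libraries of a set lay closer together than the sets did, so that number does not hold here and the 6 cannot be set against it. In the esc libraries, esc itself was at 4.40 RPKM in library 2-1 and between 3.56 and 3.66 RPKM in the others. Library 1-2 stood apart for E(z), at 17.4 RPKM against 16.5 to 16.6 RPKM, and for RpS20, at 6998 RPKM against 6888 to 6904 RPKM. The proneural gene ase was at 4.97 RPKM in esc library 1-1 against 5.48 to 5.52 RPKM, and Prm at 354 RPKM in esc library 2-1 against 328 to 332 RPKM. In OrgR, RpS10a was at 6.66 RPKM in library 1-1 against 7.62 to 7.67 RPKM. Each of these gaps was small beside the difference between the genotypes in esc, ase, Prm and RpS10a, and no library stood apart in more than 2 of the groups.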

How the results depend on the processing

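Centring on the median gene and the crossed block were chosen after the data were seen, as was the test by the count of falls after rescaling. The number of changed genes, 5537, ranged from 2087 to 5752 when a library or a set was left out, the low values all coming from a left-out set, which leaves 1 residual degree of freedom. Title numbers gave no sign of pairing the genotypes, as deviations of libraries with the same number correlated at -0.24 to -0.35 across genes. Libraries of a set were nearly alike, so these values restate 1 contrast between sets and do not exclude pairing. With the set number as a replicate block 2467 genes changed, and with set numbers crossed 6717. In all these settings and the other scalings, pseudocounts, filters and models, no gene changed in both had the opposite sign. The 2-fold count stayed between 1298 and 1961. Of the gene lists, 11 passed as deposited, 0 with an estimated correlation and 6 with fry; over the other settings 9 to 14 passed. The gene nos turned from 0.53 to -0.029 after quantile normalization (adjusted p = 0.882, range over its alternatives 0.00142 to 0.882); the cause was not tested. Of 111 named genes, 19 lost their call under median-of-ratios scaling, 8 besides nos after quantile normalization and 26 to 38 without a set. esc, lab, Ubx and Abd-B passed in all 28 settings, with highest adjusted p of 0.021, 0.00662, 0.0131 and 0.00797. Each library was also rescaled to the same exonic signal outside the genes that rose 2-fold. Those genes held 2.16% to 2.74% of exonic signal in OrgR and 10.7% to 12.3% in esc. Over all tested genes, with those that rose 2-fold included, 2390 then rose and 1769 fell. The excess of falls over all tested genes thus depends on the scaling, though it also ended without any 1 set and with the set block. Rises and falls among the other genes alone were not counted. The median of these other genes moved from -0.26 to -0.131 and so was not brought to 0. Leaving out only genes that rose lowers this median by itself, so a value below 0 does not show a fall beyond the effect of read share.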

Other observations

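The groups and tests of this part were chosen after the results were seen, except the tests of pool age, of the scaling for the Hox genes, of the 100 kb around esc and of the splits. Genes were grouped into 67 families of at least 7 tested members by the letters of their symbol, and each was tested for more rises or falls than other genes by Fisher's exact test, adjusted over 134 tests; genes are not independent replicates. Beyond cuticle families, rises were enriched in the Osi genes, which encode transmembrane proteins of cuticle-secreting cells (16 of 18 rose, adjusted p = 4.32e-08), with Osi6 from 1374 to 5155 RPKM and Osi7 from 339 to 1753 RPKM. They were also enriched among tetraspanin genes (Tsp, 18 of 31, adjusted p = 0.00013), UDP-glycosyltransferase genes (Ugt, 9 of 11, adjusted p = 0.000412), cytochrome P450 genes (Cyp, 28 of 57 with 10 falls, adjusted p = 5.37e-05) GstD glutathione transferase genes (6 of 9, adjusted p = 0.0349), and Spn serpin genes (10 of 18, adjusted p = 0.0135, with 6 rises and 4 falls after quantile normalization). Histone genes, which have many near-identical copies, had the smallest p (His, 58 of 96 rose, adjusted p = 4.68e-15), but after quantile normalization their median was -0.03 and 23 rose. Genes of the dpr family of neuronal cell surface proteins rose in 12 of 18 cases (adjusted p = 0.000436), though in as few as 3 under another scaling. Falls were enriched among Mediator subunit genes (MED, 23 of 25, adjusted p = 1.88e-08), Cdc genes (9 of 9, adjusted p = 0.000414), Rrp genes, named after ribosomal RNA processing (7 of 8, adjusted p = 0.0172) and proteasome regulatory subunit genes (Rpn, 10 of 12, adjusted p = 0.00365). They were weaker among Vps (15 of 26, adjusted p = 0.0408), Nup (12 of 19, adjusted p = 0.0376) and Taf genes (9 of 13, adjusted p = 0.0437). Apart from the histone genes, the medians of these families kept their sign under each scaling, but after other scalings as few as 9 MED, 4 Cdc, 2 Rrp, 2 Taf and 0 Rpn, Vps and Nup genes fell.

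Some genes were near absence in one genotype. Those at or below 0.1 RPKM in all OrgR libraries and at least 1 RPKM in all esc libraries numbered 68, of which 47 have a number-only symbol; the others included the protease gene yip7 (0.0715 to 26.5 RPKM) and TwdlK (0.0313 to 23.4 RPKM). The reverse held for 5 genes, CG43136 (4.71 to 0.00675 RPKM), CG8476 (2.71 to 0.018 RPKM), mthl8 (2.31 to 0.001 RPKM, the floor of the table), CG32437 (1.76 to 0.0025 RPKM) and CG32440 (1.74 to 0.0235 RPKM). CG32437 and CG32440 are neighbours on chromosome arm 3L, from 21357683 to 21359867 and from 21360179 to 21361229. Differences in strain background between OrgR and the mutant stock were not tested. Some single genes known from the ecdysone response were looked up, while the Eip family, named after induction by ecdysone, was not enriched (2 of 7 rose, 2 fell, median -0.14). The nuclear receptor gene ftz-f1 went from 0.372 ± 0.052 to 40.5 ± 1.4 RPKM (log2 change 4.92 ± 0.11, adjusted p = 0.00026), with 29.4% of its exonic bases shared with a noncoding gene. Its upstream regulator Hr3 went from 242 to 149 RPKM (-0.70, adjusted p = 0.0175), with 82.7% of its exonic bases shared with other genes. The ecdysone-dependent cuticle genes Edg91 (0.391 to 19.6 RPKM) and Edg78E (0.644 to 8.70 RPKM) rose as well. So did 2 more of the genes looked up, and both passed under each scaling. They were Cyp18a1 (17.6 to 42.6 RPKM, log2 change 1.23, adjusted p = 0.00312) and Eip74EF, of the Eip family (2.10 to 5.66 RPKM, 1.11, adjusted p = 0.00386). The Hox cofactor gene exd fell with hth (150 to 84.5 RPKM, -0.81, adjusted p = 0.0212), but did not pass after 2 of the other scalings (highest adjusted p = 0.0514).

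The rise of late cuticle genes was weighed first. The scaling is argued against, since the list's median log2 change was 3.67 or more under each of 3 other scalings. For a larger share of epidermal cells, the late cuticle median was set against that of the other epidermis and cuticle genes. It exceeded theirs by 3.45 (95% bootstrap interval 2.42 to 4.51). More epidermis would raise both alike only if both lists were confined to it, and grh of the second list is also a neural progenitor gene here. Still, the medians of the 2 lists were 3.92 and 0.47 on the log2 scale. A gap of this size argues against a larger share of epidermal cells as the only cause for these late cuticle genes. A part of the rise from such a share is not excluded. Older embryos in the esc pools may account for the rise, but the test could not decide it. Across 10477 other genes, the difference between the OrgR sets correlated with the esc effect at r = 0.246. This was under the limit set beforehand for pool age and above the limit set against it. The difference between the esc sets correlated with the esc effect at r = -0.562. Set 1 minus set 2 was 0.07 for the late cuticle list and 0.42 for the muscle list in OrgR, and -0.65 and -0.07 in esc, so the set differences were unlike and are not shown to be age, and pool age cannot be told apart from an effect of the genotype, which stays open as well.

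The opposite moves of Abd-B, lab and Ubx were weighed next. The scaling is argued against, as 3 of 3 genes kept direction and call under each of 3 other scalings. Under older esc pools, the difference between OrgR sets scaled to the whole esc effect may give part of the changes, and it gave 0.166 of that of Ubx and shares of the opposite sign for Abd-B (-0.066) and lab (-0.049). These shares are under the limit set beforehand against pool age, but that limit took the OrgR difference to be one of age, which its late cuticle value of 0.07 does not show, and 1 pair of sets gives it no error, so pool age cannot be told apart from the genotype here either; within esc, set 1 minus set 2 was -0.65 for the late cuticle list and 0.24 for Abd-B. An effect of the loss of esc on these genes remains an untested explanation.

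The fall of esc together with its neighbours was the last. A wide deletion on both homologs is argued against, since the 12 tested genes within 100 kb had a median of 0.241 above all genes. This median says less about a wide deletion on a single homolog, as 5 of the 12 rose. A small deletion may account for the run crol, CycY, esc and Pde1c. Of 10284 windows of 4 consecutive tested genes, 1 had each gene fall by at least as much, and it was this run. The run itself set that threshold, and a homozygous loss in all embryos would leave no signal, whereas crol and CycY kept 26.6 and 25.9 RPKM in esc. A deletion on only one homolog, a difference in strain background and shared regulation of these genes were not tested.

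A hypothesis that anterior and brain transcription factor genes fell further than neural progenitor genes found no support: their median was higher by 0.107 (32 and 27 genes, permutation p = 0.299 from 100000 resamples). For the number of changed genes, 1 of the 3 splits of the 4 sets, the real one, gave as many as 5537; the others gave at most 0 with limma (3 and 52 genes at an unadjusted p under 0.05), and 3 splits are too few to test chance. With the 8 libraries fitted as independent, 1 of 35 splits, the real one, gave as many as 8006, and the highest other gave 1, which excludes chance only if the libraries of a set are separate samples.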
